A study of Mus musculus with 4 samples.

How the data were processed

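The series measured polyadenylated RNA of single cells from dissociated whole ovaries of mice of 2 and 14 months, with 2 libraries per age. Per the labels' protocols, cells were captured with a droplet kit that reads the 3' end of transcripts, and libraries were pooled in groups and sequenced with a single sample index. The deposited files hold, for each library, a matrix of raw counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, after the cell calling of Cell Ranger, per the submitters' processing notes, which also name mm10 as the genome. Per the file headers, the young matrices came from Cell Ranger 4.0.0 and the old ones from 6.0.1, so this version goes with age and no fit with it as a term can be had. The headers do not say whether the ages were prepared or sequenced in separate batches. The labels give no stage of the estrous cycle.

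Of 55487 gene IDs, 55141 had a place in the GENCODE M21 annotation of GRCm38, matched by ID. A UMI was found for 33449, 32481, 33551 and 32920 genes in young 1, young 2, old 1 and old 2. Median genes per barcode were 2487, 1691, 1456 and 1916 and median mitochondrial shares 1.90%, 2.61%, 3.43% and 4.70%. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left out 293, 6, 3093 and 2000 barcodes for genes and 475, 1535, 1831 and 2413 for mitochondrial UMIs. Doublet scores came from Scrublet as implemented in scanpy. Its automatic threshold marked 0, 1, 144 and 7 cells, under 0.5% of the cells, so it was not used, and the highest scores were marked instead, at 0.8% per 1000 barcodes, which took out 1656, 1207, 1530 and 977 cells. This rule was chosen after that result was seen. The kept UMI sums were 235561043, 177364355, 135891083 and 140656127.

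Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours gave 38 clusters at a Leiden resolution of 1, with no integration across libraries. Immune cells were clustered again with 20 components. A cluster was named from marker genes fixed before the data were examined, when at least 20 cells and 3 markers passed (2-fold over the mean of the other clusters with 10 CPM added, a UMI in 10% of cells) and its 10 leading genes did not go against the name. Classes are marker-based names for clusters, not sorted cells. No annotation of cells by the authors was used here.

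UMI counts were summed over all kept cells of a library (the whole ovary) and over the cells of each class with at least 20 cells in every library. The sums were tested old against young with edgeR's quasi-likelihood test (robust fit, TMM factors, filterByExpr, Benjamini-Hochberg adjustment within a class, threshold 0.05). Standard errors are the log2 change divided by the square root of F. Interactions of age and class used library as a block. The 29 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 383 tests, with an estimated correlation and fry as alternatives. Shares of cells were compared with two-sided exact permutation tests. The change in CPM of each inflammatory gene with at least 50 UMIs was split by Kitagawa's formula into a part from class shares of UMIs and a part from levels within classes. T cell-like cells were thinned to the 10th percentile of their UMIs. Barcode copies were cells whose barcode also stood in another library with over 20 times as many UMIs, a definition chosen after seeing the data. Intervals are 95% Clopper-Pearson.

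Genes named in the text were picked by a rule fixed before the data were examined: among genes past the threshold, with a mean of at least 20 CPM, both old libraries on 1 side of both young ones and no clone, predicted or pseudogene symbol, the 10 largest changes each way in the whole ovary and the 6 largest in each class. In a class the gene also had to reach 10% of its level in the highest class, since free RNA from other cells gives low counts in every class. For a described list, up to 4 called members with the smallest adjusted p were named, and 10 inflammatory and senescence genes are given whatever their result. Exceptions are marked as chosen after their values were seen.

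The tests were also run on simulated counts with 200 changed genes. These counts were drawn from means, dispersions and library sums fitted to the real data. Of 2-fold and 4-fold changes they recovered 26% and 64% in the whole ovary, 36% and 72% in granulosa-like, 48% and 87% in stromal fibroblast-like, 34% and 88% in macrophage-like, 6% and 78% in blood endothelial-like, 43% and 86% in T cell-like and 44% and 88% in surface epithelial-like cells. In the same order 24 of 114, 5 of 113, 11 of 146, 29 of 151, 13 of 97, 10 of 139 and 17 of 149 calls were false, a share above the threshold of 5% in all but granulosa-like cells. For the interaction 21 of 131, 6 of 95 and 12 of 97 calls were false against granulosa-like, blood endothelial-like and macrophage-like cells. Replicate libraries of 1 age differed by more than counting error, with a chi-square per degree of freedom over genes of 443 between the young and 152 between the old whole-ovary sums. Alternatives were other size factors (RLE), no filter on low counts, DESeq2, the replicate number as a block, leaving out each library, keeping doublets, at least 1000 genes and at most 10% mitochondrial UMIs, thinned sums, genes at free RNA levels left out, resolutions of 0.5 and 2, and each library clustered alone. Added after seeing the data were leaving out barcode copies, clusters 3 and 18 of granulosa-like cells, cluster 13 of luteal-like cells, immune cluster 20, and the oviduct and red cell classes. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.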

Results

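Single-cell RNA-seq libraries were made from dissociated whole ovaries of C57BL/6J mice, an inbred strain, at 2 months of age (young) and at 14 months (old), with 2 libraries per age and 4 in all. The files held 14736 barcodes for young 1, 13079 for young 2, 16226 for old 1 and 13001 for old 2. Their totals were 276179576, 201953559, 169244164 and 170867171 unique molecular identifier (UMI) counts. The median barcode held 6974, 4198, 4194.5 and 6637 UMIs in that order. After filters on quality and doublets, 12390, 10332, 10258 and 8416 cells were kept. Clusters of these cells were named from marker genes fixed before the data were examined, as were the gene lists and the tests, and every class name stands for cells like that type. The title of the series places the question in the cells from which inflammation of the ageing ovary comes, so the comparisons asked which classes changed in share, which transcripts changed in the whole ovary and within classes, and which classes held the inflammatory transcripts. The labels do not say that replicate libraries came from separate animals, so each SD and p-value measures the spread between these libraries.

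Immune cells took a larger share of the old ovaries. All immune classes together made up 8.26% ± 2.32 (SD, n = 2) of kept cells in young libraries and 22.9% ± 2.67 in old ones, 2.77-fold. T cell-like cells, which carry the T cell receptor, went from 1.74% ± 0.241 to 7.81% ± 0.539, 4.50-fold, and B cell-like cells, the antibody lineage, from 0.494% ± 0.0550 to 2.63% ± 0.419, 5.32-fold. Natural killer (NK) or innate lymphoid-like cells went from 1.33% ± 0.00278 to 3.11% ± 0.494, macrophage-like cells from 3.93% ± 1.88 to 7.62% ± 2.40 (3.69 percentage points higher in old, 1.99 without old 2 and 2.36 without young 1), and dendritic cell-like cells from 0.631% ± 0.230 to 1.18% ± 0.123. Neutrophil-like cells were the rarest immune class tested, at 0.138% ± 0.0239 and 0.521% ± 0.0196. In each of these classes both old libraries lay above both young ones, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries can give.

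Among the other classes, stromal fibroblast-like cells, which make the collagen framework, went from 4.34% ± 0.239 (SD, n = 2) to 8.23% ± 1.79, a difference as separate between the libraries as those of the immune classes. Granulosa-like cells, which surround the oocyte, held 56.7% ± 8.90 of young and 45.5% ± 3.64 of old cells, but this difference of -11.3 percentage points was -0.531 with doublets kept, -0.539 with the stricter cell filter, -0.736 with each library clustered alone and -4.98 without young 1. Luteal-like cells, the progesterone producers of the corpus luteum, held 9.79% ± 2.85 and 4.45% ± 1.83, a difference that turned to 0.550 percentage points higher in old with each library clustered alone. Smooth muscle-like cells held 1.08% ± 0.139 and 0.503% ± 0.229 in the main clustering and were named in no other (doublets kept, stricter cell filter, other resolutions, each library alone). Blood endothelial-like cells went from 2.39% ± 1.65 to 0.915% ± 0.370, a difference of -0.312 percentage points without young 2. The libraries did not overlap in these 5 classes, with an exact permutation p of 0.333 for each. With barcode copies left out (cells whose barcode stood in another library with over 20 times as many UMIs), granulosa-like and blood endothelial-like libraries overlapped and theca-like ones no longer did. Theca-like (9.38% ± 3.78 and 6.51% ± 0.446) and surface epithelial-like shares (1.92% ± 0.121 and 2.04% ± 0.132) overlapped, with an exact permutation p of 0.667. So did lymphatic endothelial-like (0.458% and 0.438%, exact permutation p of 1) and oocyte-like shares (0.107% and 0.0740%, exact permutation p of 0.667).

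The libraries also differed in how much neighbouring tissue and blood they held. Oviduct secretory-like cells, the lining of the egg duct, made up 10.6% of old 1 (95% Clopper-Pearson interval 10.1 to 11.3) and 2.25% of old 2 (1.94 to 2.59), against 0.121% ± 0.0342 (SD, n = 2) of young libraries. Ciliated epithelial-like cells made up 0.703% ± 0.205 of old libraries and were 0 of 12390 and 0 of 10332 young cells, which allows shares of up to 0.0298% and 0.0357% (95% Clopper-Pearson). Of the 47 ciliated-like cells in old 2, 46 had a barcode also found in old 1 with over 20 times as many UMIs. Erythroid-like cells, which carry haemoglobin transcripts, made up 9.24% of young 2 (8.69 to 9.82) and 1.42% of young 1 (1.22 to 1.64), against 0.421% ± 0.108 of old libraries. These intervals cover counting error only.

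**Figure D1:**
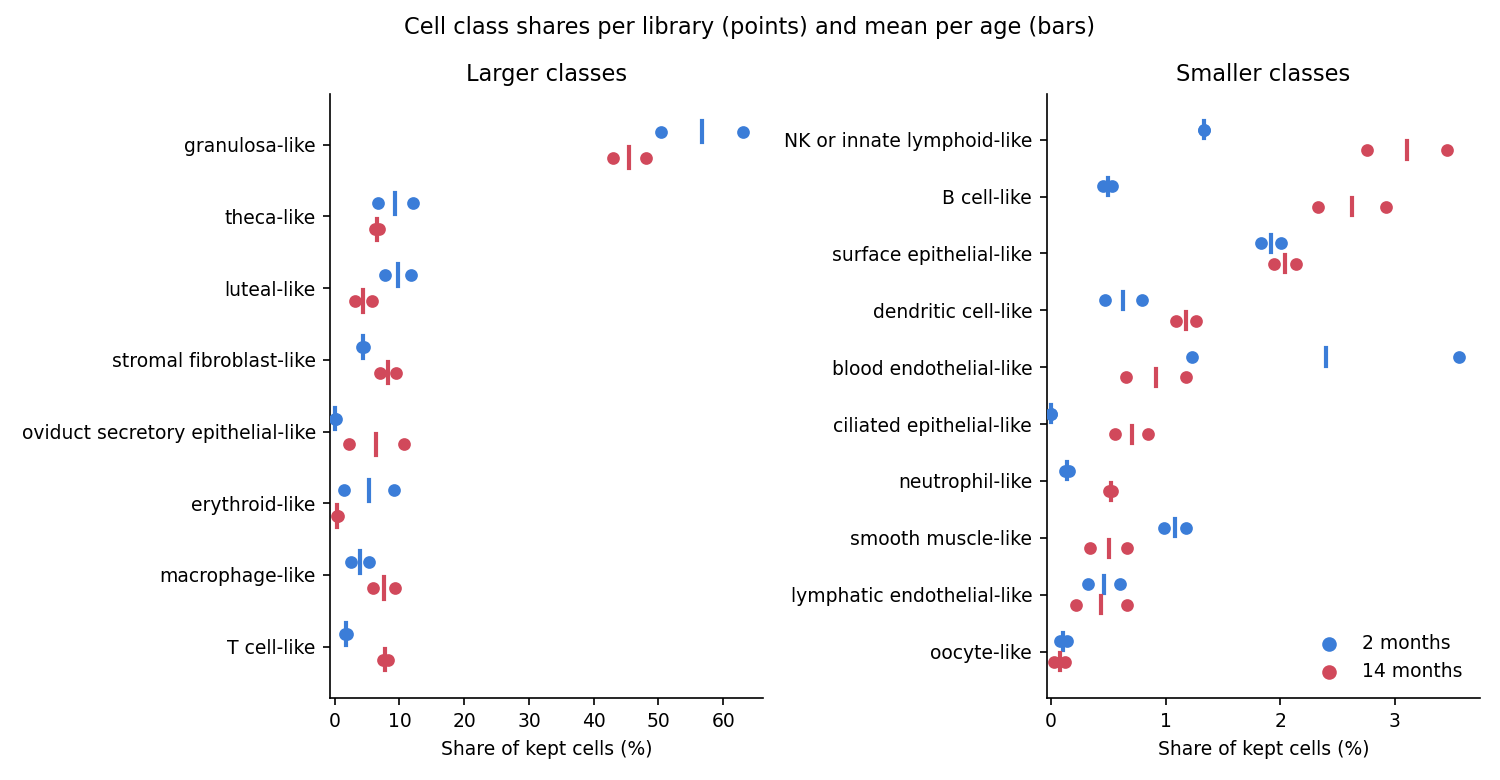
Share of kept cells (%, x axis) of each cell class in each library, with 2 months in blue and 14 months in red; points are libraries and bars are the mean of the 2 libraries of an age. T cell-like cells went from a mean of 1.74% to 7.81% and B cell-like cells from 0.494% to 2.63%.

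Within the immune compartment, T cell-like and B cell-like cells held a larger and macrophage-like cells a smaller share in old ovaries. T cell-like cells were 16.4% ± 4.40 (SD, n = 2) of young and 33.6% ± 5.82 of old immune cells, and B cell-like cells 6.21% ± 2.43 and 11.4% ± 0.559. Macrophage-like cells went from 46.5% ± 10.0 to 26.8% ± 3.48, while monocyte-like cells went from 1.83% ± 0.175 to 3.46% ± 1.21. For these 4 classes the libraries of the ages did not overlap, at the smallest exact permutation p the design allows (0.333). NK or innate lymphoid-like cells (16.6% ± 4.74 and 13.8% ± 0.379) and dendritic cell-like cells (5.41% and 5.58%) overlapped, with an exact permutation p of 1. With doublets kept, the macrophage difference turned to 1.43 percentage points higher in old, and with the stricter cell filter it was -3.65.

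T cell subsets were read at equal depth, with each cell thinned to 1954 UMIs, which left 151 and 153 young and 771 and 595 old T cell-like cells and left out 43, 44, 69 and 30. Cd8a or Cd8b1, which mark cytotoxic T cells, had a UMI in 32.5% ± 9.47 (SD, n = 2) of young and 33.8% ± 4.51 of old cells, and Cd4, which marks helper T cells, in 5.91% ± 2.74 and 3.83% ± 1.01. Neither was seen in 61.6% ± 12.2 and 62.1% ± 3.66, and both in 0% and 0.279%. Shares of Cd8, Cd4 and neither overlapped between the ages (exact permutation p of 1, 0.667 and 1) and those of both genes did not (0.333). Cd4 did not overlap without thinning or in another thinning run, the one without barcode copies (6.91% ± 0.401 and 4.05% ± 0.504), with an exact permutation p of 0.333 in each. Without thinning the shares were 34.0% and 37.9% for Cd8 and 9.46% and 6.56% for Cd4. In B cell-like cells, which should lack these genes, the thinned background was 0% and 3.44% for Cd8 and 0.962% and 0.870% for Cd4, and 1.82%, 7.42%, 1.52% and 3.10% without thinning. Median depths were 3942 and 4738 UMIs in young and 4301.5 and 4520 in old T cell-like cells, and 3063.5, 4446, 4244 and 4679.5 in B cell-like cells. Thinned shares with a UMI of Trdc were 7.26% ± 5.65 and 14.8% ± 0.937, and of Gzmk, a granzyme of cytotoxic cells, 10.2% ± 9.68 and 19.9% ± 0.522, both higher in both old libraries, against 0% and 0% for Trdc and 1.09% and 1.299% for Gzmk in B cell-like cells. Those of Il17a, 1.32% and 2.91%, were also higher in both old libraries, and those of Foxp3, a regulatory T cell gene, were 0.989% and 0.149%, from 1 or 2 cells per library (1.09% and 0.220% in B cell-like cells), while Pdcd1 (20.1% and 18.9%) and Tox (15.1% and 15.6%) overlapped.

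In the whole ovary, old libraries held more transcripts of Ccl2, Tnfaip3 and Trem2 and fewer of Tex14. Ccl2, a chemokine that draws monocytes, was at 11.8 CPM (UMI counts scaled to the same total in each library) in young and 63.7 in old libraries, a log2 change of 2.40 (SE 0.19). Tnfaip3, a feedback inhibitor of NF-kB signalling, went from 8.79 to 43.4 CPM (2.26, SE 0.13) and Trem2, a lipid receptor of macrophages, from 11.03 to 50.7 (2.16, SE 0.12). Tex14, needed for the bridges between germ cells, fell by 1.96 on the log2 scale (SE 0.12), from 47.0 to 12.5 CPM. By edgeR their adjusted p-values were 0.0424, 0.0421, 0.0421 and 0.0421, all near the threshold. The genes are ENSMUSG00000035385 (Ccl2, chromosome 11, 82035571 to 82037453), ENSMUSG00000019850 (Tnfaip3, chromosome 10, 19000910 to 19015657), ENSMUSG00000023992 (Trem2, chromosome 17, 48346401 to 48354147) and Tex14 (chromosome 11, 87405065 to 87555823) in GRCm38, each annotated as protein coding.

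Of 23186 genes tested in the whole ovary, 275 passed, 212 higher and 63 lower in old. The largest rises were of Wfdc18 (0.204 to 165 CPM), S100g (3.83 to 334), Plet1 (1.92 to 66.1) and Wfdc2 (1.69 to 55.3), the first of which was at 281 CPM in old 1 and 48.4 in old 2, the order of the oviduct secretory-like shares. These 4 missed the threshold without young 1 or young 2 (adjusted p of 0.181 to 0.275, edgeR). S100a9, a neutrophil protein, rose by 2.54 (log2), S100a4 by 2.12 and Trbc2, a T cell receptor chain, by 2.01. Besides Tex14 the largest falls were of Cables1 (-1.57), Rhobtb1 (-1.41), Apoa1 (-1.31), Adamts19 (-1.31), Cnmd (-1.22), Hpgd (-1.13), Prss23 (-1.05), Arxes2 (-1.02) and Ide (-1.0004). Sums of all cells move with class shares as well as with expression. Without old 1 all of these falls but that of Tex14 missed the threshold, without young 2 all but those of Tex14, Cables1 and Apoa1, and Ide missed it without any of the 4. Without young 1, young 2, old 1 and old 2 in turn, 0, 162, 138 and 1061 genes passed by edgeR, and with doublets kept 0, where 3470 (without young 1) and 4888 (doublets kept) were under an unadjusted p of 0.05. DESeq2 on all libraries called 2509 genes, and with barcode copies left out edgeR called 42. On simulated counts of the whole ovary 24 of 114 calls were false.

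By camera with a preset correlation, and not with an estimated one (adjusted p of 0.535 for each), several inflammatory lists were higher in the whole ovary. Of 29 chemokines measured, 5 were higher over all genes and 15 when adjusted over the list alone, with a median log2 change of 1.45; Ccl2, Ccl12 (2.17), Ccl3 (1.51) and Xcl1 (1.03), a chemokine for dendritic cells, passed. Of 39 cytokines, 4 were higher (21 adjusted over the list alone, median 0.99), among them Tnf (2.45), Ifng (1.86), Ltb (2.70) and Csf3 (5.02). Of 40 NF-kB targets, 7 were higher and 1 lower (25 and 1 adjusted over the list alone, median 0.91): Tnfaip3, Nfkbid (1.67) and Vcam1 (1.86) rose, while Nos2, which makes nitric oxide, fell by 1.64. Of 39 cytokine and chemokine receptors 8 were higher (21 and 1 lower adjusted over the list alone, median 1.02), led by Il7r (2.24), Ccr7 (2.32), Cxcr6 (2.18) and Il2ra (2.42). Of 32 genes of lipid-laden phagocytes 5 were higher (17 and 1 lower adjusted over the list alone, median 0.67), with Trem2, Abcg1 (2.21), Lgals3 (1.78) and Itgax (2.32). Others called so were age-associated T cell genes (5 of 22 higher, 18 adjusted over the list alone, median 1.55), complement (3 of 28, 11 adjusted over the list alone, median 1.02) and senescence-associated secretory genes (8 of 71, 29 higher and 1 lower adjusted over the list alone, median 0.63). None of the named genes passed without young 1. Of the list members, Abcg1, Csf3, Lgals3, Nos2 and Vcam1 also missed the threshold without young 2, Ccl3, Tnf and Cxcr6 without old 1, Ccl12, Ifng, Il2ra, Itgax and Nfkbid without either, and Xcl1 without any of the 4 (adjusted p of 0.0504 to 0.181, edgeR).

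Further lists had few or no single genes past the threshold in the whole ovary. Of 14 genes of MHC class II presentation, 0 passed edgeR's test over all genes and 13 were higher adjusted over the list alone, with a median of 1.58 (adjusted p of 0.568 with an estimated correlation). Of 35 cell division genes, 0 passed and 24 were lower adjusted over the list alone (median -0.54, adjusted p of 0.549 with an estimated correlation). Steroidogenesis gave 1 higher gene of 32 over all genes and 1 adjusted over the list alone: Cyp17a1, the enzyme that starts androgen synthesis, rose by 1.90, from 22.5 and 24.7 to 75.3 and 105 CPM, and missed the threshold without young 1 or young 2 (median -0.21, mean 0.02, camera direction down at an adjusted p of 0.65, or 0.809 with an estimated correlation). Of 85 and 91 lists called higher and lower by camera in 383 tests of list and class, 0 were called with an estimated correlation.

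Genes to be given whatever their result included Ccl5, a T cell chemokine (82.2 to 254 CPM in the whole ovary, log2 1.59), Cdkn2a, which encodes the cell-cycle inhibitor p16 (0.869 to 5.43, 2.61), Cxcl13, the B cell chemokine (0.323 to 1.42, 2.08), H2-Aa of MHC class II (134 to 416, 1.60) and Il1b (54.7 to 111, 0.99). None passed by edgeR (adjusted p of 0.0828, 0.103, 0.105, 0.136 and 0.206). The sums include oviduct cells, too few in young to test. Il6 was at 1.5 and 1.49 CPM (log2 -0.06, adjusted p of 0.947, turning to 0.62 without young 1) and Cdkn1a, a p53 target, at 78.7 and 105 (0.35, adjusted p of 0.700, turning to -0.16 without young 2). Tnf went from 1.25 to 7.04 CPM and C3, the central complement protein, from 7.93 to 24.3, and both passed, though C3 only without old 2 when 1 library was left out. In the class where each was highest among those it was tested in, at either age, none passed: Tnf in T cell-like (1.70) and dendritic cell-like cells (0.05), Ccl2 in macrophage-like cells (0.64, 453 to 672 CPM), Ccl5 in NK or innate lymphoid-like cells (0.12), C3 in surface epithelial-like cells (-0.67), Cdkn2a in stromal fibroblast-like cells (0.64), H2-Aa in dendritic cell-like cells (0.26) and Cxcl13 in macrophage-like cells (0.74, turning to -0.60 without young 2 and -0.46 without old 2).

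**Figure D2:**
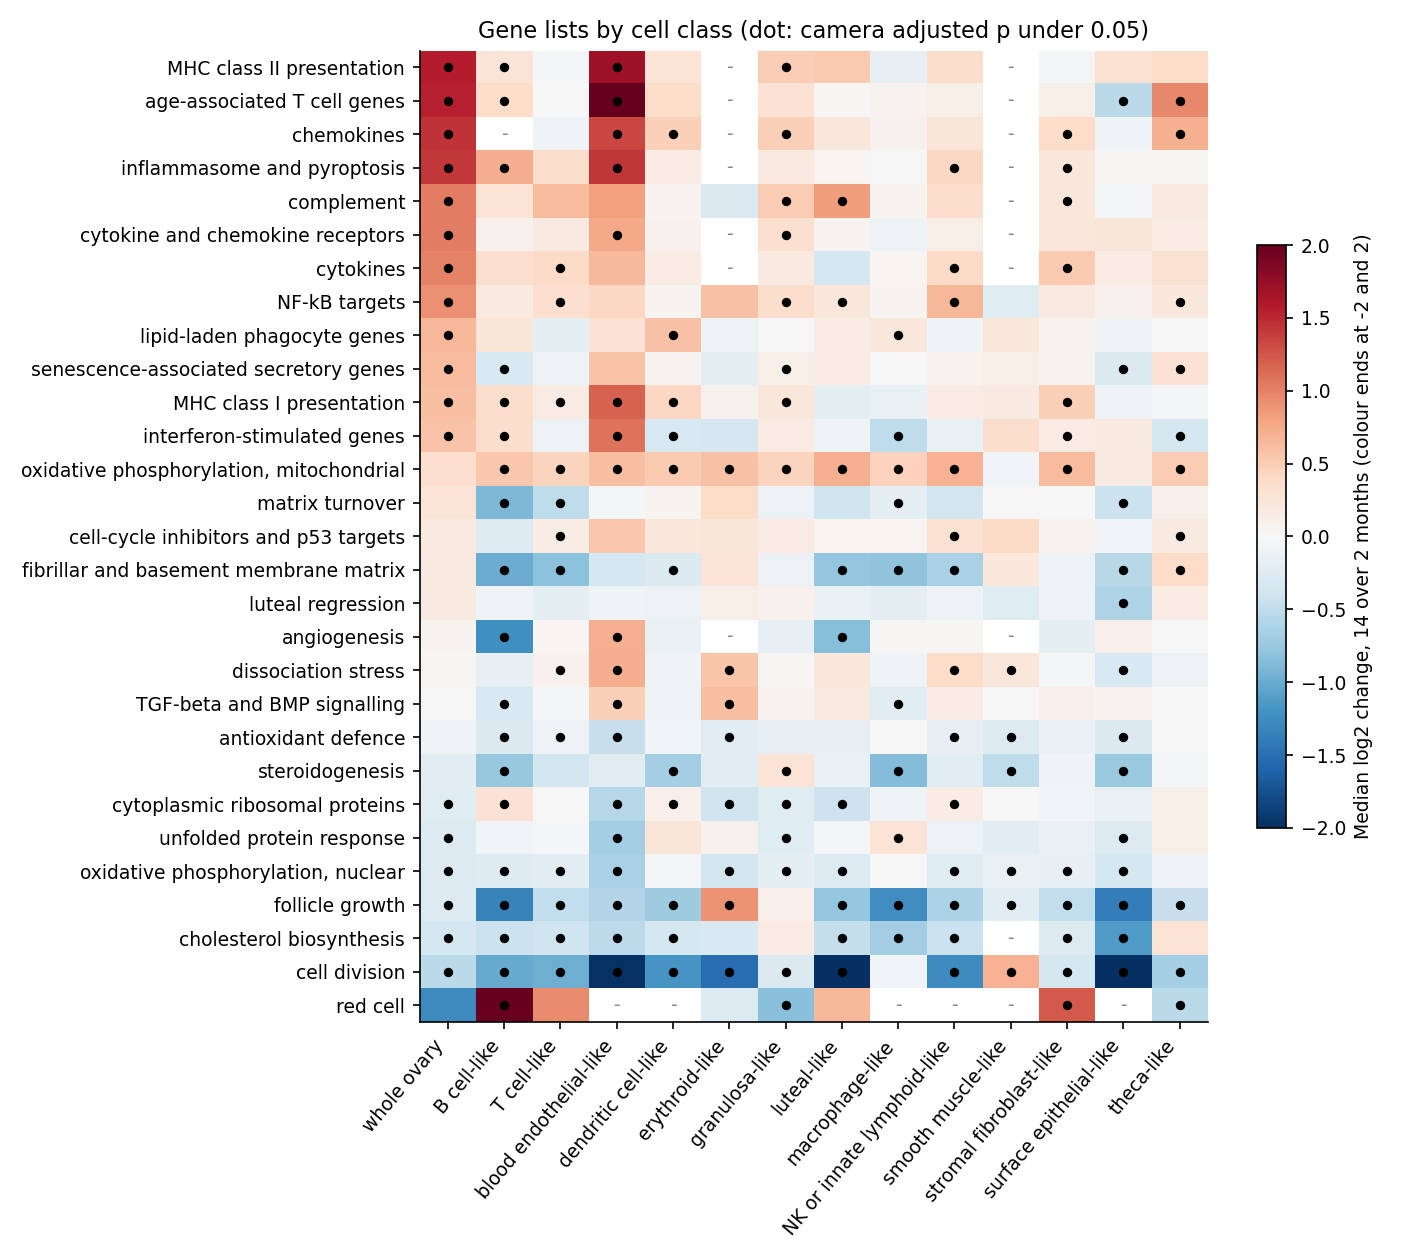
Median log2 change, 14 over 2 months, of the measured members of each gene list (rows) in the whole ovary and in each cell class (columns), with a dot where camera with a preset correlation gave an adjusted p under 0.05 and a dash where fewer than 5 members were measured. Chemokines had a median of 1.45 in the whole ovary and cell division genes of -1.98 in blood endothelial-like and -2.15 in surface epithelial-like cells.

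Most of the rise in inflammatory transcripts came with the shares of the cell classes. Of 110 chemokine, cytokine, complement and MHC class II genes, 82 were higher in both old libraries and 3 (Mif, Il34 and Tslp) lower in both. In 68 of the 82 the part of the change from class shares was larger than the part from levels within classes, and in 14 the reverse held. All 14 MHC class II genes were higher, all 14 with the larger part from shares; chemokines gave 22 of 30 (16), cytokines 26 of 39 (23) and complement 20 of 27 (15). Macrophage-like cells held the largest share of UMIs of 41 of the 82 genes in old ovaries. T cell-like cells did of 11, granulosa-like of 9, stromal fibroblast-like of 8, oviduct secretory-like of 5 and ciliated-like of 1. These oviduct classes were not left out of the split. With genes low in a class left out, 77 were higher (67 with the larger part from shares, 10 within classes) and 6 lower. Without each library in turn 86 to 93 were higher (63 to 74 and 13 to 27) and 5 to 9 lower.

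Single genes differed in where their rise came from. Of the 51.9 CPM that Ccl2 gained, 31.6 came from class shares and 20.4 from levels within classes, and macrophage-like cells held 65.8% of its UMIs in young and 71.5% in old ovaries. Ccl5 gained 195 CPM from shares and changed by -23.2 within classes, and its main class went from NK or innate lymphoid-like cells (46.0%) to T cell-like cells (50.6%). For Il1b the parts were 96.2 and -40.0 CPM and for Cd74 744 and -91.1. Cxcl1 went the other way, with -5.18 CPM from shares and 62.0 within classes, and granulosa-like cells held 65.4% of it in old ovaries. Masp1, a complement protease, likewise had parts of -10.8 and 37.1 CPM, with 91.7% in granulosa-like cells. The main class of C3 went from surface epithelial-like (77.0%) to oviduct secretory-like cells (41.4%), which also held 93.8% of Csf3. The main class of Il34 was granulosa-like in young (51.4%) and stromal fibroblast-like in old ovaries (56.2%). These splits have no test.

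**Figure D3:**
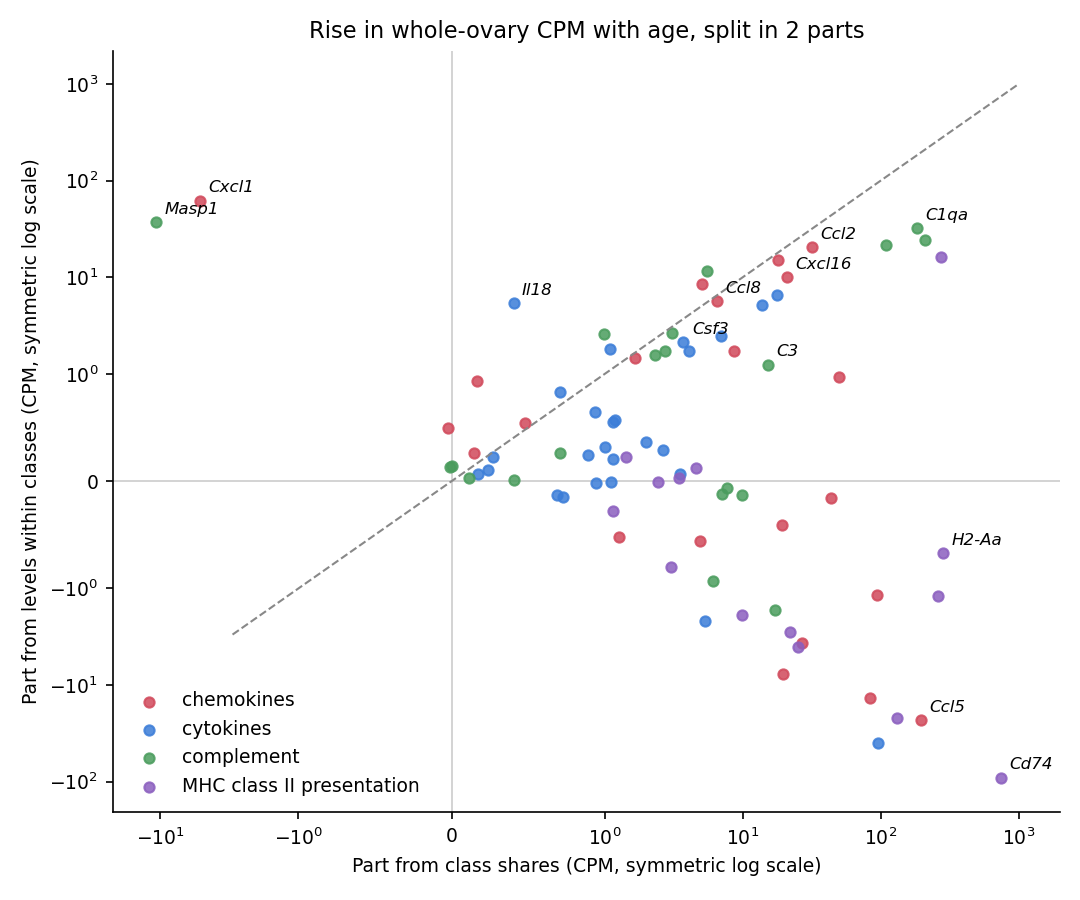
Change in whole-ovary CPM from 2 to 14 months of the 82 inflammatory genes higher in both old libraries (points, coloured by family), split into the part from class shares (x axis, CPM, symmetric log scale) and the part from levels within classes (y axis, same scale); the dashed line marks equal parts. In 68 genes the share part was larger, and Cxcl1 and Masp1 lie where it was negative.

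In granulosa-like cells, old ovaries held more transcripts of Lhcgr. Lhcgr, the luteinizing hormone receptor (ENSMUSG00000024107, chromosome 17, 88716481 to 88791990, GRCm38, protein coding), rose from 25.8 to 174 CPM. Its log2 change was 2.74 (SE 0.21, adjusted p of 0.0175, edgeR). Of 20238 genes tested, 98 were higher and 24 lower, and 107 and 55 without young 1 and 97 and 67 without young 2. Pde10a, which breaks down cyclic nucleotides, rose by 3.19, Pappa, a protease that frees insulin-like growth factors, by 3.41, and Rhox8, a homeobox gene, by 1.87. Tex14 (-1.67), Agt, the angiotensin precursor (-1.44), Ntng1 (-1.39), Ccn2, a matricellular target of Hippo signalling (-1.74), Cd200 (-1.295) and Cald1 (-1.48) fell. Pappa missed the threshold without young 1 (adjusted p of 0.201) and young 2 (0.197), and Ccn2, Cald1 and Cd200 missed it without old 1 or old 2 (0.0517 to 0.113 by edgeR). Cald1 turned to 0.034 with the stricter cell filter and 0.052 with each library clustered alone, where 1 gene passed in this class. Clusters 6 and 2 held 27.1% and 18.5% of young and clusters 4, 5 and 18 held 28.0%, 17.9% and 13.1% of old granulosa-like cells.

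The steroidogenesis list was called higher in granulosa-like cells by camera with a preset correlation and not with an estimated one (adjusted p of 0.535), as were NF-kB targets. In the former 4 of 31 genes were higher over all genes and 7 higher and 1 lower adjusted over the list alone, with a median of 0.28. Cyp17a1 rose by 2.34 and Fdx1, the electron carrier of mitochondrial steroid enzymes, by 1.09, and Lhcgr and Prlr, the prolactin receptor (1.53), are also members, but Cyp17a1 stood under 10% of its level in the highest class, where free RNA can reach. NF-kB targets gave 2 higher of 38 (8 higher and 1 lower adjusted over the list alone, median 0.36): Cxcl1 (1.31) and Tnfaip3 (1.85), the latter also under 10% of the highest class. Fibrillar and basement membrane matrix gave 0 higher and 1 lower of 62 (3 lower adjusted over the list alone, median -0.11, adjusted p of 0.627 with an estimated correlation). Without 1 library, Fdx1 (old 1, old 2), Prlr (young 1, young 2), Cxcl1 (young 2) and Tnfaip3 (old 2) missed the threshold, at adjusted p-values of 0.0517 to 0.0878 by edgeR.

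Luteal-like, theca-like and smooth muscle-like cells gave 0 genes by edgeR, of 14902, 14115 and 2191 tested. At an unadjusted p under 0.05 there were 1099, 991 and 121 genes, and DESeq2 called 192, 125 and 2. In luteal-like cells 24 of 35 cell division genes were lower adjusted over the list alone, with a median of -2.17 (adjusted p of 0.535 with an estimated correlation), while the CPM summed over these genes was 3572 and 3045 in young and 2359.5 and 5459 in old libraries. In theca-like cells 11 of 35 were, with a median of -0.68 (0.568), and in smooth muscle-like cells the median was 0.70 with 0 genes either way (0.568). Leaving out libraries in turn gave 28 genes in luteal-like cells without young 2, 130 and 88 in theca-like cells without old 1 and old 2, and 3, 10, 31 and 34 in smooth muscle-like cells. In luteal-like cells cluster 13, of which 96 of the 96 cells in young 2 were barcode copies, held 28.0% of young and 0.188% of old cells, and cluster 11 17.7% and 46.8%. On simulated counts of that class the test recovered 0% of 2-fold and 8% of 4-fold changes.

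Stromal fibroblast-like cells gained transcripts of Penk and Car3. Penk, the enkephalin precursor (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, GRCm38, protein coding), rose from 4.80 to 67.3 CPM. Its log2 change was 3.88 (SE 0.19, adjusted p of 0.000789, edgeR). Car3, a carbonic anhydrase abundant in fat and muscle, was at 1.05 and 0.208 CPM in young and 75.7 and 60.2 in old libraries. Of 13835 genes 57 were higher and 10 lower, a split that was 159 and 129 without young 1 and 80 and 62 without young 2. Besides Lars2 (2.72) and mt-Rnr1 (2.46), the histone genes H4c4 (2.66) and H1f4 (2.10) rose. Spry1, an inhibitor of growth factor signalling (-1.22), the imprinted gene Peg3 (-1.16) and Nfib, a transcription factor (-1.01), fell. H4c4 missed the threshold without young 1 or young 2 (adjusted p of 0.185 and 0.182), Spry1 without old 1 (0.117), and Peg3 and Nfib without old 1 or old 2 (0.051 to 0.194, edgeR).

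In stromal fibroblast-like cells the matrix list as a whole did not move: 1 of 64 genes was higher over all genes and 2 adjusted over the list alone, with a median of -0.10, a mean of 0.00 and an adjusted p of 0.63 (0.891 with an estimated correlation). The member that passed was Postn, a matrix protein of remodelling tissue (1.76). Complement gave 1 of 19 (4 adjusted over the list alone, median 0.23), Colec12, a scavenger receptor (1.49), and chemokines 1 of 20 (1 adjusted over the list alone, median 0.37), Cxcl5, at 0.263 and 0.208 CPM in young and 9.07 and 3.71 in old libraries. These last lists were called with a preset correlation and not with an estimated one (adjusted p of 0.535 and 0.538). Without young 1 and young 2, 288 and 142 genes passed in this class, and without old 2 149; Cxcl5 missed the threshold without young 1 (adjusted p of 0.0525, edgeR) and young 2 (0.101).

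In blood endothelial-like cells of old ovaries Fbln2, a fibulin of elastic matrix, rose by 3.21 (log2, adjusted p of 0.00132, edgeR). It stood at 30.4 and 31.7 CPM in young and 243 and 286 in old libraries. Of 9023 genes, 296 were higher and 295 lower, in libraries of 152 and 368 young and 67 and 99 old cells. Stmn2 rose by 4.23 (4.15 to 80.0 CPM) and Mal by 4.18 (5.84 to 107). Cytl1 (2.34 and 0.288 to 49.0 and 78.1 CPM), Bmx, a kinase of arterial endothelium (2.34 and 3.75 to 49.0 and 32.1), and Ace, the angiotensin-converting enzyme (1.56 and 4.04 to 24.5 and 58.6), rose from few counts. Shmt2, of mitochondrial folate metabolism (-3.01), and Acta2, smooth muscle actin (-4.10), fell. Acta2 missed the threshold without old 1 or old 2 (adjusted p of 0.151 and 0.184, edgeR) and Ace without old 2 (0.0573). Without young 2, old 1 and old 2, 200, 1980 and 229 genes passed, and without young 1 347; the split without old 1 was 794 higher and 1186 lower.

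Camera called cell division, interferon-stimulated, MHC class I and age-associated T cell genes in blood endothelial-like cells with a preset correlation and none of them with an estimated one (adjusted p of 0.535 for each). Of 35 cell division genes 28 fell (34 adjusted over the list alone, median -1.98), with Hells (-2.52), Mcm7 (-2.52) and Ccna2 (-2.38) among them. Of 54 interferon-stimulated genes 15 rose (30 adjusted over the list alone, median 1.09), led by Rsad2 (3.07), Iigp1 (2.37), Parp14 (2.12) and Sp100 (1.65). Of 21 genes of MHC class I presentation 8 rose (13 adjusted over the list alone, median 1.18), among them H2-T23 (2.41) and Tapbp (1.58); H2 genes share sequence, so single H2 values are uncertain. Of 8 age-associated T cell genes 5 were higher (6 adjusted over the list alone, median 2.95), and 5 of the 8 were at free RNA levels, far below the highest class. Angiogenesis gave 6 higher and 2 lower of 32 (10 and 3 adjusted over the list alone, median 0.71, adjusted p of 0.708 with an estimated correlation), with Vegfc (1.96), Plvap (2.60), Hey1, a Notch target (2.65), and Thbs1 (-2.03, under 10% of the highest class). Matrix gave 5 higher and 2 lower of 42 (6 and 3 adjusted over the list alone, median -0.34, adjusted p of 0.934 with an estimated correlation): Fbln2, Fbln5 (2.27), Mgp (2.48) and Eln, elastin (1.86). Sp100 and Tapbp missed the threshold without young 1 (adjusted p of 0.0985 and 0.099, edgeR), Tapbp without young 2 (0.0868), Eln and Thbs1 without young 1 (0.0569 and 0.0512), Mgp without young 2 (0.0919) and Hey1 without old 2 (0.0897).

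Macrophage-like cells of old ovaries gained transcripts of Pmepa1 and Nr1h3. They lay in clusters 23 and 25, in proportions that differed between the ages. Pmepa1, an inhibitor of transforming growth factor β signalling (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533, GRCm38, protein coding), rose from 32.5 to 127 CPM. Its log2 change was 2.08 (SE 0.19, adjusted p of 0.00862, edgeR). Gdf3, a ligand of that family, rose by 2.57, Nr1h3, the liver X receptor α that senses oxysterols, by 1.66, Tgm2, a transglutaminase, by 1.65, and the histone genes H1f4 and H2ac20 by 1.66 and 1.60. Of 11986 genes, 24 were higher and 134 lower, with the largest falls in Slc38a5 (-3.06), Bex4 (-2.39), Serpine2 (-2.23), Grb14 (-2.18), Snhg18 (-1.97) and Tnni3 (-1.96). Of 30 follicle growth genes 6 were lower here (1 higher and 21 lower adjusted over the list alone, median -1.24, adjusted p of 0.535 with an estimated correlation), with Inha (-1.87), Esr2 (-1.76, under 10% of the highest class) and Fshr (-2.97). Amh, a granulosa gene, went the same way in this class, from 56.9 and 58.4 to 14.4 and 5.72 CPM, and at an unadjusted p under 0.05 Slc38a5 was lower in 10 of 12 classes, Tnni3 in 10 of 13 and Bex4, Serpine2 and Inha in 9 of 13. With genes at free RNA levels left out, 68 genes passed, and with doublets kept 8. On simulated counts of this class 29 of 151 calls were false.

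In macrophage-like cells 3 of 78 interferon-stimulated genes fell (23 adjusted over the list alone, median -0.51, adjusted p of 0.587 with an estimated correlation): Oasl2 (-1.80), Ifi203 (-0.88) and Rtp4 (-1.24). Of 24 cholesterol biosynthesis genes 2 fell (3 adjusted over the list alone, median -0.69, adjusted p of 0.642 with an estimated correlation), Fdps (-1.16, under 10% of the highest class) and Msmo1 (-0.94). Of 22 chemokines 1 rose (2 adjusted over the list alone), Ccl7 (1.16), a monocyte chemokine, while the median was 0.09, the mean -0.15 and the adjusted p 0.21 (0.623 with an estimated correlation). Oasl2 passed without each library in turn. Without 1 library Ifi203 and Msmo1 (any of the 4), Rtp4 (young 2, old 1), Fdps (young 2, old 2), Ccl7, Gdf3 and Grb14 (old 1), Tgm2 and Fshr (young 1, young 2) and Esr2 (young 1, old 1) missed the threshold, at adjusted p-values of 0.0502 to 0.132 by edgeR. Without old 2, 252 genes passed.

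In T cell-like cells of old ovaries Gzmb, a cytotoxic protease, fell by 1.54 on the log2 scale (adjusted p of 0.00260, edgeR). It stood at 63.8 and 69.2 CPM in old libraries. Ret rose from 8.14 to 48.0 CPM (2.87, SE 0.36), Actn2 by 2.04, Gcnt2 by 1.97, and Kcnk1 and Hbegf by 1.83 each. Of 9966 genes 83 were higher and 91 lower, over cells of clusters 15 and 16. Cluster 15, with Actn2 among its leading genes, held 10.0% of young and 25.5% of old cells. Ube2c (-2.04), Tpx2 (-1.95) and Rrm2 (-1.82) of dividing cells fell, as did Derl3, a plasma cell gene (-1.78), Tdrd5 (-2.82) and Apoa1 (-1.79). Derl3 was lower in 9 of 12 classes and Apoa1 in 12 of 13 at an unadjusted p under 0.05. Of 35 cell division genes 14 fell (22 adjusted over the list alone, median -0.98), with Stmn1 (-1.58), Cdk1 (-1.52), Birc5 (-1.58) and Cenpf (-1.71), the last pair under 10% of the highest class, and of 30 NF-kB targets 4 rose (7 adjusted over the list alone, median 0.34): Nfkbiz (1.39), Nfkbia (1.47), Bcl2a1b (1.11) and Zc3h12a (1.18). Both lists were called with a preset correlation and neither with an estimated one (adjusted p of 0.535 and 0.627). Age-associated T cell genes did not move as a list: 3 of 22 rose and 1 fell (3 and 2 adjusted over the list alone, median -0.00, mean 0.05, adjusted p of 0.53, or 0.864 with an estimated correlation), with Eomes (1.26), Bhlhe40 (0.96) and S100a4 (0.86) up and Gzmb down.

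In T cell-like cells 372, 300, 56 and 63 genes passed without young 1, young 2, old 1 and old 2. Ret, Actn2, Gzmb, Tdrd5, Stmn1, Cdk1, Nfkbiz and Nfkbia passed each time. Eomes, S100a4, Gcnt2, Rrm2 and Zc3h12a missed the threshold without either old library (Gcnt2 and Zc3h12a also without young 2, Rrm2 without young 1) and Ube2c, Tpx2, Kcnk1, Birc5, Cenpf and Apoa1 without old 1, while Hbegf, Bcl2a1b, Bhlhe40 and Derl3 missed it without old 2, at adjusted p-values of 0.052 to 0.293 by edgeR.

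NK or innate lymphoid-like cells lay in clusters 27 and 32, in proportions that differed between the ages. Nfkbiz, a nuclear regulator of NF-kB (ENSMUSG00000035356, chromosome 16, 55811375 to 55838899, GRCm38, protein coding), rose from 171 to 611 CPM. Its log2 change was 2.21 (SE 0.19, adjusted p of 0.000621, edgeR). Lztfl1 rose by 2.48, Epas1 by 2.23, Lars2 by 3.05 and mt-Rnr1 by 2.85. Of 8252 genes 107 were higher and 42 lower. Pclaf (-2.28), Cdk1 (-2.26), Amh (-2.15), Apoa4 (-2.10) and Apoa1 (-1.96) were among the largest falls. Amh, a granulosa gene, and Apoa1 were lower in 12 of 13 classes at an unadjusted p under 0.05. Pclaf was in 11 of 13, Cdk1 in 10 of 13 and Apoa4 in 10 of 12. Of 28 NF-kB targets 7 rose (11 adjusted over the list alone, median 0.67, adjusted p of 0.535 with an estimated correlation), with Nfkbiz, Nfkbia (1.45), Tnfaip3 (1.52) and Bcl2a1b (1.25), and 7 of 33 cell division genes fell (25 adjusted over the list alone, median -1.26, adjusted p of 0.535 with an estimated correlation), with Stmn1 (-1.59), Cenpf (-2.13, under 10% of the highest class) and Top2a (-1.53). Of 34 genes known to rise during tissue dissociation 6 rose (14 adjusted over the list alone, median 0.36, adjusted p of 0.568 with an estimated correlation), with Zfp36 (1.57), Btg2 (1.18), Nr4a1 (1.497) and Jun (1.02). Of 25 cytokine and chemokine receptors 3 rose (3 adjusted over the list alone, median 0.12, adjusted p of 0.775 with an estimated correlation): Il1rl1, the interleukin-33 receptor (1.52), Il2ra (1.21) and Il10ra (1.02). With the stricter cell filter 0 genes passed by edgeR's test (604 at an unadjusted p under 0.05, 103 by DESeq2 on the usual filter), and Cdk1, Stmn1, Cenpf, Top2a, Pclaf and Amh turned to between 0.0068 and 0.98. Without young 1 and young 2, 435 and 310 genes passed. Apoa1 (adjusted p of 0.073, edgeR), Jun (0.054) and Il10ra (0.126) missed the threshold without old 1, and Il10ra without old 2 (0.0581).

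Dendritic cell-like cells of old ovaries gained transcripts of Zmynd15 and Ccl5. Zmynd15, which encodes a zinc finger protein (ENSMUSG00000040829, chromosome 11, 70459433 to 70466202, GRCm38, protein coding), rose from 19.8 to 170 CPM. Its log2 change was 3.37 (SE 0.25, adjusted p of 0.000103, edgeR). Ccl5 rose from 411 to 2285 CPM (2.73, SE 0.30), Epsti1, an interferon-induced gene, by 2.69 and H2-Eb2 by 2.68. Of 7260 genes 62 were higher and 24 lower, with Ccna2 (-2.17), Hpgd (-2.06), Cdca8 (-1.97), H2ax (-1.65) and Tsc22d3, a glucocorticoid-induced gene (-1.65), among the falls. Of 14 chemokines 3 rose (3 higher and 3 lower adjusted over the list alone, median 0.48, adjusted p of 0.538 with an estimated correlation): Ccl5, Cxcl16 (1.54) and Ccl7 (3.76). Of 34 cell division genes 2 fell (22 adjusted over the list alone, median -1.18, adjusted p of 0.535 with an estimated correlation). Stmn1 was at -1.72. Of 29 receptors Ccr7 (1.48) and Il15ra (2.21) rose (2 adjusted over the list alone, median 0.09, adjusted p of 0.708 with an estimated correlation). Without young 1 and young 2, 42 and 38 genes passed, and without old 1 and old 2 214 and 153; with doublets kept 3 did. Without young 1 and old 2 the split was 20 and 72 higher and 22 and 81 lower. Ccna2, Ccr7, H2-Eb2, H2ax, Hpgd and Il15ra missed the threshold without either young library, Cdca8 and Tsc22d3 without young 1 and Ccl7 without young 2 (adjusted p of 0.0599 to 0.201, edgeR).

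In B cell-like cells 6 of 24 follicle growth genes fell (14 adjusted over the list alone, median -1.34, adjusted p of 0.535 with an estimated correlation), with Inha (-1.76), Serpine2 (-2.42), Hsd17b1 (-1.80) and Gja1 (-1.28). Amh, a granulosa gene, went the same way there, from 355 and 82.6 to 23.9 and 21.3 CPM, and Inha and Serpine2 were lower in 9 of 13 classes at an unadjusted p under 0.05. H1f4, a linker histone (ENSMUSG00000051627, chromosome 13, 23620629 to 23622558, GRCm38, protein coding), rose from 119 to 466 CPM. Its log2 change was 2.32 (SE 0.27, adjusted p of 0.00142, edgeR). Of 7365 genes 15 were higher, with mt-Rnr1 (2.30), Lars2 (2.16) and mt-Rnr2 (1.65) next, and 70 lower, with Zfp385b (-3.18), Fscn1, an actin-bundling protein (-3.07), and Slc38a5 (-2.98) first. Of 27 cell division genes 5 fell (10 adjusted over the list alone, median -1.001, adjusted p of 0.535 with an estimated correlation), with Stmn1 (-1.66), Birc5 (-2.80, under 10% of the highest class), Ube2c (-1.90) and Tubb5 (-1.001), and of 21 genes of MHC class I presentation 1 rose (5 adjusted over the list alone, median 0.36, adjusted p of 0.574 with an estimated correlation), Psmb9 of the immunoproteasome (1.36). Without young 1 and young 2, 193 and 292 genes passed. The split of higher and lower was 44 and 34 with doublets kept, 42 and 42 without old 2 and 178 and 143 with no low count filter. Fscn1 missed the threshold without young 1 (adjusted p of 0.0547, edgeR), Psmb9 without old 1 (0.12), mt-Rnr2 without old 2 (0.0528), Birc5 and Tubb5 without either old library (0.151 to 0.225) and Zfp385b without young 1, old 1 or old 2 (0.353 to 0.751).

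Surface epithelial-like cells, which cover the ovary, had 269 genes higher and 448 lower of 11395 in edgeR's test. Amh, a granulosa gene, went from 332 and 132 to 9.43 and 7.46 CPM in this class, the same way as the lists that fell. Mme (ENSMUSG00000027820, chromosome 3, 63241537 to 63386030, GRCm38, protein coding) rose from 20.2 to 154 CPM. Its log2 change was 3.01 (SE 0.22, adjusted p of 5.06e-07, edgeR). Pappa rose by 2.27, Ly6a by 2.13, Rbp4, a retinol carrier, by 1.97 and Syne1 by 1.93. Apoa1 (-3.60), Ccnb2, a mitotic cyclin (-3.47), Cenpa (-3.23), Apoa4 (-3.08), Cnmd (-3.04) and Tdrd5 (-3.02) fell most. Of 35 cell division genes 26 fell (34 adjusted over the list alone, median -2.15, adjusted p of 0.535 with an estimated correlation), with Top2a (-2.72) and Stmn1 (-1.75). Summed over these genes, the log2 ratio of old over young CPM was -1.43, and 0.32 with the free RNA part, scaled from Amh, taken off. Of 23 cholesterol biosynthesis genes 13 fell (18 adjusted over the list alone, median -1.13, adjusted p of 0.535 with an estimated correlation): Fdps (-2.14), Mvk (-1.83), Insig1 (-1.51) and Msmo1 (-1.45). Of 27 steroidogenesis genes 9 fell (11 adjusted over the list alone, median -0.74, adjusted p of 0.535 with an estimated correlation), with Mrap (-2.93) and Fdx1 (-1.90), both under 10% of the highest class, and Nr5a2 (-1.88), and of 48 matrix genes 9 fell (1 higher and 12 lower adjusted over the list alone, median -0.55, adjusted p of 0.535 with an estimated correlation), with Mfap2 (-2.70), Fbln1 (-1.72), Fbn2 (-1.70) and Plod2 (-1.31). Without young 1, young 2 and old 2, 379, 1259 and 468 genes passed; Fbn2 and Plod2 missed the threshold without young 1 (adjusted p of 0.0504 and 0.0687, edgeR).

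Erythroid-like cells, which make few transcripts besides globins, held genes of granulosa cells that moved with age. Grem1, an inhibitor of bone morphogenetic proteins, went from 6.49 to 156 CPM (log2 4.48), Inhba, the activin βA subunit, from 478.5 to 2693 (2.24), Cyp19a1, aromatase, changed by 2.15 and Nppc by 1.80 (log2), while Amh, anti-Müllerian hormone of small follicles, went from 206 to 18.2 (-3.60). Of 3961 genes 64 were higher and 27 lower by edgeR. Of 24 follicle growth genes 6 were higher and 1 lower (13 and 3 adjusted over the list alone, median 0.90, adjusted p of 0.574 with an estimated correlation), and of 25 cell division genes 8 were lower (20 adjusted over the list alone, median -1.52, adjusted p of 0.535 with an estimated correlation), with Birc5 (-2.81, under 10% of the highest class) and Stmn1 (-1.996). With doublets kept and with each library clustered alone, 0 genes passed by edgeR (484 and 560 at an unadjusted p under 0.05, 37 by DESeq2 on the usual cells), and without young 1 and old 2 278 and 151 did. The split was 49 higher and 61 lower without young 2 and 58 and 63 without old 1.

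The change with age in stromal fibroblast-like cells differed from that in other classes when the difference itself was tested. Against granulosa-like cells 411 of 19273 genes had an interaction of age and class by edgeR. It was 352 of 13989 against blood endothelial-like cells and 343 of 14887 against macrophage-like cells. Of these, 302, 140 and 231 had log2 changes of opposite direction, 0, 2 and 1 of these passed the test within both classes, and 164, 98 and 129 lay above the free RNA level in both. The genes that follow were chosen after their values were seen. Wnt4, a ligand of ovarian development, changed by 2.01 in stromal fibroblast-like and by -2.38 in blood endothelial-like cells (interaction -4.46, adjusted p of 1.305e-08, edgeR) and passed in both classes. Cyp1b1, an enzyme that hydroxylates oestrogens, changed by 1.41 in stromal fibroblast-like cells, by -1.98 in macrophage-like and by -0.47 in granulosa-like cells (interaction -3.37 and -1.85, adjusted p of 0.000136 and 2.71e-06, edgeR). Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, changed by 1.82 and by -0.58 in granulosa-like cells (interaction -2.38, adjusted p of 8.97e-08, edgeR). Without young 1, young 2, old 1 and old 2 the counts were 741, 575, 704 and 469 against granulosa-like, 164, 114, 2073 and 511 against blood endothelial-like, and 409, 56, 428 and 527 against macrophage-like cells.

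Pairs of libraries of the same age shared far more cell barcodes than pairs of different ages. Young 1 and young 2 shared 2939 barcodes and old 1 and old 2 shared 2316, against 51 to 66 for the 4 pairs of different ages. The smaller of the UMI totals was a median of 2.54% of the larger in the young pair (10th to 90th percentile 2.37 to 2.77) and 2.04% in the old pair (1.65 to 2.32). Such copies made up 10.7% and 9.99% of kept cells in young 1 and young 2 and 6.47% and 6.06% in old 1 and old 2, but 0.982%, 1.60%, 0.596% and 0.456% of their UMIs. B cell-like, T cell-like, NK or innate lymphoid-like and neutrophil-like cells held 0 copies.

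**Figure D4:**
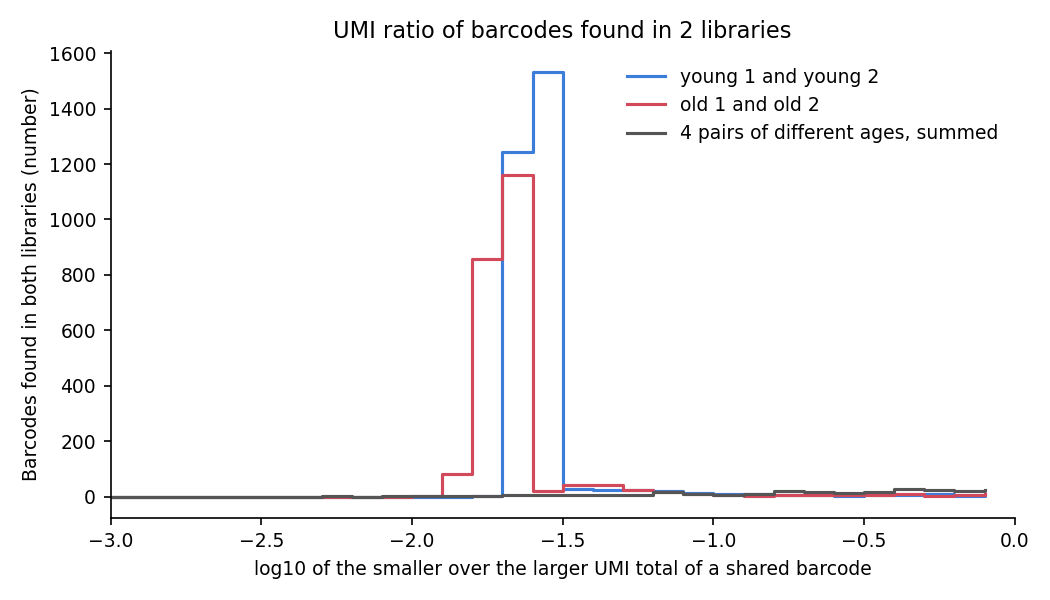
Number of barcodes found in both libraries of a pair (y axis) by the log10 ratio of the smaller to the larger UMI total (x axis), for the young pair (blue), the old pair (red) and the 4 pairs of different ages summed (grey). The young and old pairs peak at a ratio near 2.54% and 2.04%, where the pairs of different ages have almost no barcodes.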

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

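The tests of free RNA on dendritic cell-like and blood endothelial-like and on T cell-like and NK or innate lymphoid-like cells, the tests on RNAs without a poly(A) tail and the tests on shared barcodes were chosen only after the result was seen.

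The effect of age differed between classes by a test of the difference itself, with 411 genes in stromal fibroblast-like against granulosa-like cells, 352 against blood endothelial-like and 343 against macrophage-like cells. A cluster without a name was found in old ovaries and no young one (cluster 36, 129 cells of old 1 once barcode copies are left out). A second such cluster held 25 cells of old 2 (cluster 37, Car1 at 1080 and Klf1 at 321 CPM, both genes of red cell precursors) and was in 0 young cells. Another held 95 immune cells of old libraries (immune cluster 20, 15 in old 1 and 80 in old 2) and was in 0 young cells.

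Cell division genes were lower in old cells of most classes, with a median log2 ratio of -0.869 over 12 classes. Free RNA from dividing granulosa cells of young ovaries may bring this difference in part of the classes: with that part taken off, scaled from Amh, the median over the classes with a value was -0.01953 (quartiles -0.676 and 0.392). In erythroid-like and surface epithelial-like cells the ratio went from -1.07 and -1.43 to 0.847 and 0.319. B cell-like cells had no value, since in young 1 the part to take off, 4732 CPM, was over the 3397 CPM measured, so the scaling from Amh can take off too much. In dendritic cell-like and blood endothelial-like cells a fall was left. The highest ratio left over the main run, the stricter cell filter, doublets kept, barcode copies left out and each library clustered alone was -0.547. Both old libraries lay below both young ones (dendritic cell-like cells had too few cells in the last run). This argues against free RNA as the whole cause only as far as the scaling from Amh holds. In T cell-like and NK or innate lymphoid-like cells free RNA cannot be told apart, because the ratios left, -1.43 and -0.643 in the main run, did not hold in every setting: T cell-like cells had -0.2148 with each library clustered alone, and NK or innate lymphoid-like cells had no value with doublets kept or the stricter filter, where the ratio before was 0.177. Fewer dividing cells in old ovaries stay open as well: the share of cells with at least 2 of 6 division markers at equal depth was lower in both old libraries in 12 of 13 classes (39.6% to 7.65% in blood endothelial-like cells, 11.2% to 1.82% in T cell-like cells, smooth muscle-like cells being the exception), though free RNA can enter these shares and neutrophil-like cells, which do not divide, had 6.25% and 3.48%. Age itself and the Cell Ranger version that goes with it were not tested apart.

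RNAs without a poly(A) tail were higher in old cells of most classes: the median of class medians was a log2 change of 2.30 for mitochondrial RNAs without a tail, against 0.512 for mitochondrial messenger RNAs, and 0.505 for replication-dependent histones. More cells copying their DNA would raise division genes with the histones. This cannot be told apart, because of free RNA: the cell division median was under -0.3 in 8 of the 11 classes with a histone median above 0, but division genes stayed under -0.3 with the free RNA part taken off in only 3 of the 9 with a value, and were above 0 in 5. A library or sequencing batch that goes with age cannot be told apart from age, because every library of an age shares it: the mitochondrial median was above 0 in 13 of 13 classes. A change of these RNAs with age in the cells themselves also stays open, as untested.

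Libraries of 1 age shared barcodes at a fixed UMI ratio. Chance reuse of barcodes is argued against by 38.76 times as many shared barcodes as in pairs of different ages, in the pair with fewer. Reads carried between libraries sequenced together are a candidate explanation: the ratio of the 90th to the 10th percentile of the UMI ratio was at most 1.406, against 51.1 for shuffled young and 63.7 for shuffled old pairs, and 96.3% of copies in the young pair and 93.2% in the old pair fell in the class of their larger partner (63.5% and 50.7% by chance). That route gives weak copies of cells, so classes seen in old 2 only as copies, such as the 46 of 47 ciliated epithelial-like cells, may not have been in that library. What carried the reads was not tested, and age offers no biological explanation for a shared barcode.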

How the results depend on the processing

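Leaving out barcode copies, clusters 3 and 18, cluster 13, immune cluster 20 or the oviduct and red cell classes was chosen after seeing the data. With 2 libraries per age, a lone library left in 1 age was assumed to vary like the other age. The direction of class shares held in 208 of 225 values, turned in 10 and was absent in 7 for want of a named cluster. These were smooth muscle-like in every other clustering, ciliated epithelial-like at a resolution of 0.5 and oocyte-like with each library clustered alone. The direction of immune shares held in 64 of 72 and of T cell subsets in 18 of 24. All 12 values of the sources (genes higher in old, and of these with the larger share part) kept their count within 1.5 times. Those with the larger part within classes and those lower moved by more, to 27 and 9 without young 1. Counts of genes moved by over 1.5 times in 94 of 179 values within classes and 11 of 13 in the whole ovary. Of 264 calls of named genes, those of the interaction included, 143 passed without each library in turn; over all settings 2940 of 3559 values of these genes kept direction and call, 599 lost the call or had no adjusted p and 20 turned sign. The cause of each move was not tested unless it is named.

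Genes past the threshold, where the count moved by over 1.5 times, were as follows. With no filter on low counts there were 1521 in the whole ovary, 321 in B cell-like, 469 in T cell-like, 1200 in blood endothelial-like, 395 in dendritic cell-like, 187 in erythroid-like, 1590 in granulosa-like, 201 in luteal-like, 790 in macrophage-like, 411 in NK or innate lymphoid-like, 13 in smooth muscle-like, 748 in stromal fibroblast-like, 1161 in surface epithelial-like and 397 in theca-like cells. DESeq2 gave 2509 in the whole ovary and 41, 89, 306, 37, 752, 192, 250, 2, 192, 291 and 125 in B cell-like, T cell-like, blood endothelial-like, erythroid-like, granulosa-like, luteal-like, macrophage-like, smooth muscle-like, stromal fibroblast-like, surface epithelial-like and theca-like cells; its split of higher and lower was 515 and 237 in granulosa-like and 75 and 216 in surface epithelial-like cells. With doublets kept the counts were 0 in the whole ovary and 387, 3, 0, 8, 89, 107, 212 and 61 in blood endothelial-like, dendritic cell-like, erythroid-like, macrophage-like, NK or innate lymphoid-like, stromal fibroblast-like, surface epithelial-like and theca-like cells. The stricter cell filter gave 457 in the whole ovary and 37, 52, 7, 86, 0, 360 and 9 in B cell-like, dendritic cell-like, erythroid-like, macrophage-like, NK or innate lymphoid-like, surface epithelial-like and theca-like cells. Thinned sums gave 31, 88, 21, 52 and 85 in B cell-like, T cell-like, dendritic cell-like, erythroid-like and NK or innate lymphoid-like cells. Each library clustered alone gave 354, 39, 1774, 0, 1, 63 and 41 in B cell-like, T cell-like, blood endothelial-like, erythroid-like, granulosa-like, macrophage-like and stromal fibroblast-like cells. Whole-ovary counts were 634 without the oviduct and red cell classes and 42 without barcode copies. Macrophage-like cells gave 68 with genes at free RNA levels left out, where fewer genes were tested, luteal-like cells 2 without cluster 13 and smooth muscle-like cells 2 with RLE size factors. The counts of 0 are by edgeR; at an unadjusted p under 0.05, 4888 genes in the whole ovary and 484 in erythroid-like cells with doublets kept, 604 in NK or innate lymphoid-like cells with the stricter filter and 560 in erythroid-like cells with each library clustered alone.

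The libraries of the ages share replicate numbers in the labels, but only as numbers, and the deviations of equal numbers had a correlation of -0.1 over genes. The fit with the replicate number as a block gave 696 genes in the whole ovary and 38, 249, 292, 97, 243, 7, 340 and 16 in B cell-like, dendritic cell-like, granulosa-like, macrophage-like, NK or innate lymphoid-like, smooth muscle-like, stromal fibroblast-like and theca-like cells, and turned Il6 in the whole ovary to 0.045 and Tnf in dendritic cell-like cells to -0.065 (log2).

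Leaving out 1 library at a time gave 0 to 1061 genes in the whole ovary, 84 to 292 in B cell-like, 56 to 372 in T cell-like, 200 to 1980 in blood endothelial-like, 38 to 214 in dendritic cell-like, 110 to 278 in erythroid-like, 0 to 28 in luteal-like, 152 to 252 in macrophage-like, 154 to 435 in NK or innate lymphoid-like, 3 to 34 in smooth muscle-like, 67 to 288 in stromal fibroblast-like, 379 to 1259 in surface epithelial-like and 0 to 130 in theca-like cells. For the interaction it gave 469 to 741, 114 to 2073 and 56 to 527 genes against granulosa-like, blood endothelial-like and macrophage-like cells. Differences that changed sign, in percentage points, ranged from -0.244 to 0.205 for lymphatic endothelial-like and -0.0781 to 0.0115 for oocyte-like cells, -0.895 to 1.24 for dendritic cell-like and -6.25 to 0.456 for NK or innate lymphoid-like shares of immune cells, and -5.44 to 7.95 for Cd8 and -8.08 to 9.18 for neither gene among T cell-like cells. Log2 changes did so for Il6 (-0.50 to 0.62) and Cdkn1a (-0.16 to 1.22) in the whole ovary, Il1b (-0.62 to 0.053), Cdkn1a (-0.47 to 0.37) and Tnf (-0.63 to 0.50) in dendritic cell-like, Cxcl13 (-0.60 to 8.69) in macrophage-like, Ccl5 (-0.26 to 0.44) in NK or innate lymphoid-like and Il6 (-0.46 to 0.37) in stromal fibroblast-like cells, and none of these was called.

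A direction that held can hide a difference that nearly went: granulosa-like shares, -11.3 percentage points in the main run, were -0.531 with doublets kept, -0.539 with the stricter filter and -0.736 with each library clustered alone. Of the others, those of macrophage-like cells went from 3.69 to 1.99 without old 2, of theca-like cells from -2.88 to -0.202 without young 1, of blood endothelial-like cells from -1.48 to -0.312 and of erythroid-like cells from -4.91 to -0.9996 without young 2, of oviduct secretory-like cells from 6.32 to 2.12 without old 1, and of neutrophil-like cells from 0.383 to 0.0611 with each library clustered alone. Luteal-like shares turned sign, to 0.550 percentage points, with each library clustered alone, and lymphatic endothelial-like shares to 0.00755 without the oviduct and red cell classes. Unnamed cells turned to -13.9 with doublets kept, -5.53 with the stricter filter, -2.20 and -7.52 at resolutions of 0.5 and 2, and -15.6 with each library clustered alone. Among immune cells, dendritic cell-like shares turned to -2.41 with the stricter filter and -0.237 and -0.745 at resolutions of 0.5 and 2, macrophage-like shares to 1.43 with doublets kept, neutrophil-like shares to -0.430 with the stricter filter and unnamed cells to 2.29 at a resolution of 0.5. Unnamed immune cells were at -22.2 with doublets kept and -8.01 with the stricter filter. T cell-like cells with neither gene turned to -1.83 without thinning, and Cd8 to -0.490 in the run without barcode copies, where no T cell-like cell was a copy and the random thinning alone differed. With doublets kept, log2 changes turned for Il6 in the whole ovary (0.27) and stromal fibroblast-like cells (0.26), Tnf in dendritic cell-like cells (-0.29), and Hmgb2 (1.58), Pclaf (0.000397), Cenpw (0.17), Birc5 (1.25) and H2ac8 (1.26) in erythroid-like cells. With the stricter filter they turned for Nppc (-0.70), Hmgb2 (0.037), Nf1 (-0.37), Rian (-0.11) and H2ac8 (0.19) in erythroid-like cells, Cald1 (0.034) in granulosa-like cells, and Cenpf (0.029), Stmn1 (0.0068), Pclaf (0.98), Cdk1 (0.28), Amh (0.36), Ccl5 (-0.55) and Top2a (0.91) in NK or innate lymphoid-like cells. With each library clustered alone they turned for Hmgb2 (0.10) and H2ac8 (0.13) in erythroid-like, Cald1 (0.052) in granulosa-like, Cxcl13 (-1.27) in macrophage-like and Il6 (0.042) in stromal fibroblast-like cells. Of 176 list calls, 0 held with an estimated correlation and 2 by fry. Direction turned in 0, 3, 2 and 2 of the 176 without young 1, young 2, old 1 and old 2. No value could be had with each library clustered alone in dendritic cell-like, NK or innate lymphoid-like and smooth muscle-like cells, nor with doublets kept, the stricter filter or barcode copies left out in smooth muscle-like cells, for want of cells.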

Other observations

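The test of Sertoli cell genes was written before its result was seen, while the description of the clusters was chosen after the data were seen.

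An immune cluster without a name was found in old ovaries and in 0 young cells. The clustering of all cells put immune cluster 20 in the macrophage-like class, but that of immune cells left it unnamed, with 4 macrophage markers past the rule and 0 of them, against 1 of monocytes, among its leading genes. It had 15 cells in old 1 and 80 in old 2 besides copies, and 0 of the 322 and 543 young macrophage-like cells. It held 2986 CPM of Fcgr4, an IgG receptor of non-classical monocytes, against 131 in the other macrophage-like cells, 1740 against 177 CPM of Fabp4, a fatty acid binding protein, and 503 against 5.38 CPM of Cd300e, a monocyte receptor. Cdkn2a, which encodes p16, was at 263.5 against 1.40 CPM and the B cell chemokine Cxcl13 at 216 against 1.59 CPM. C1qa, a complement gene of resident macrophages, was at 3218 against 3798 CPM and Adgre1, which encodes F4/80, at 73.3 against 198. These values describe cells grouped by their expression, so they carry no test.

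In old 1, 129 cells formed a cluster with 0 cells in young libraries, and the 13 in old 2 were all barcode copies. It held 5996 CPM of Cst12, 3618 of Aard, 2140 of Defb36, 1670 of Cst9, 648 of Cldn11, a tight junction protein of the testis, and 341.5 of Sox9, the transcription factor of Sertoli cells. Dmrt1, a keeper of testis identity, was at 45.3 CPM, Shbg at 186, Tsx at 104, Mro at 262 and Gata1 at 60.9. Amh was at 81.2 CPM against 576.5 in granulosa-like cells and Rhox5, a gene of mouse Sertoli cells, at 0.521. The hypothesis that these cells resemble Sertoli cells was tested on 16 listed Sertoli cell genes that did not lead the cluster: 6 of them were over 2 times the CPM of every named class, which may go with that reading but lies between the bounds set in advance, so such cells cannot be told apart from granulosa cells of another state. The cluster rests on a single library.

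H1f4 was higher in old cells at an unadjusted p under 0.05 in 13 of 13 classes, and mt-Rnr1 and Lars2 in 12 of 13. Birc5, a division gene, and the histone gene H2ac8 were lower in 11 of 13 and Inha, a granulosa gene, in 9 of 13.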
